A study of Homo sapiens with 8 samples.

How the data were processed

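Transcript levels were measured in SKBR3, a human HER2-positive breast cancer cell line, with 8 Affymetrix expression arrays of 54675 probe sets, 1 array per condition. Per the labels' protocols, cells were held for 4 h in medium with 10% charcoal-stripped serum, from which steroids are largely removed, and then treated for 3 h. The conditions were untreated cells, 0.1% ethanol (the vehicle of estradiol), estradiol at 1e-06 M, E2-BSA (estradiol coupled to bovine serum albumin) at 1e-06 M, the carrier BSA at 1e-06 M, G15 at 1e-05 M, and E2-BSA at 1e-06 M together with ICI or with G15, each antagonist at 1e-05 M. Each array was placed in its group from its own title. The title of the series speaks of a time course, and all arrays analysed here are of 3 h. An array of ICI alone was not analysed here.

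Per the labels' protocols, total RNA was isolated on Nucleospin II columns, labelled with biotin and hybridized as the array maker prescribes. The summarization of probes, the normalization and any software are not given in the sources used here. The deposited values lie between -2.27 and 7.85, and on every array the median over all probe sets is 0.00. In every probe set at most 4 of the 8 arrays lie above 0 and at most 4 below, in 48.3% of the probe sets at least 2 arrays hold an exact 0, and in 2860 probe sets none does. The bound of 4 is that of values centred on a median for each probe set, so that the absolute level is removed. The repeated 0 need ties or a further step, and neither that step nor the arrays used for the centring are given in the sources used here. The deposited values were read as log2 values. Their base is not given in the sources used here: base 10 would put the largest differences beyond the range of a 16-bit scanner, and base e cannot be excluded, in which case all differences below are on that scale and the folds are larger. Values as deposited were used, since the 25th, 50th and 75th percentiles differed between arrays by 0.0962, 0.00 and 0.0643, each under the limit of 0.1 set beforehand.

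The loss of level changed the plan in several places. A filter on low values, the choice of the probe set with the highest mean for each gene, and random lists matched on mean level were fixed before the data were examined, and none of them can be computed from centred values. No filter was therefore applied, a gene was represented by the mean of all its probe sets, and random lists were matched on the number of probe sets per gene, in bins up to 6 or more. Some of these genes are not expressed in the cells, and their differences are noise. The 62 control probe sets were left out. Names came from the platform annotation: 41091 probe sets carried 1 gene, 1801 several and 11721 none. Of those with 1 gene, 41037 were matched to a current gene record by their gene identifier. The analysis used 19775 genes, of which 9252 had 1 probe set and 10523 had several. No genome position is given, because the values carry none.

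With 1 array per condition the comparisons have no replicate error, no test and no p-value, and p-values come only from the limma alternative below, which pools the ligand-free arrays; the number of arrays limits the precision. A difference is the log2 value of the first array minus that of the second. Genes were counted where it was at least 1.00 in size, that is 2-fold, higher and lower apart. The difference between the BSA and untreated arrays, which received no hormone and no antagonist, was used as the spread when alternatives were judged, with an SD over genes of 0.166; it is the closer of the pairs of this kind with the untreated array, since ethanol minus untreated had 0.304. Named genes were chosen by a rule fixed before the data were examined: in the 5 comparisons with a hormone or an antagonist against its own reference, up to 12 genes with the largest positive and up to 12 with the largest negative difference among those at 2-fold with a difference larger than the range of the untreated, ethanol and BSA arrays; in the other 3 comparisons up to 3 each way; and members of the gene lists at 2-fold and the receptors. For estradiol minus ethanol 1 lower gene that this rule selects is left unnamed. List members named below 2-fold are examples chosen after their values were seen, and other genes outside this rule are marked where they appear. Gene lists, 27 in all, were also fixed beforehand from general knowledge. For each list and comparison the median difference was placed among the medians of 10000 random lists, and a list stood apart below percentile 2.5 or above 97.5. This percentile describes these arrays and is not a p-value. Some lists share members. Pearson and Spearman correlations were taken across genes, which are not independent replicates, between differences that share no array.

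Alternatives were median centring of each array, other comparators, and a limma fit with the untreated, ethanol and BSA arrays as 3 samples of 1 group. The probe set with the largest SD, probe sets without shared-sequence suffixes, a threshold of 1.5-fold, comparators without the ethanol array and limma without it were added after seeing the data. The counting rule, the list percentiles and limma were tested on simulated arrays of 19775 genes, whose noise was the difference between the BSA and untreated arrays, scaled to 1 array and shuffled over genes. That noise leaves out the larger spread of the ethanol array (0.304 for ethanol minus untreated) and any spread particular to a gene. The rates that follow hold for such noise only and do not say how often changes on the real arrays would be found. For the simulated estradiol minus ethanol comparison the 2-fold rule recovered 48.0% of 50 genes planted at a log2 change of 1.00 and 100.0% of 50 planted at 1.50, 2.00 and 3.00 each, and took in 2 of 19575 unchanged genes. For simulated estradiol against the ligand-free arrays, limma recovered 96.0% of the genes planted at 1.00 and called 23 unchanged genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.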

Results

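Early transcript levels were compared in SKBR3 cells given free estradiol, albumin-coupled estradiol (E2-BSA) or antagonists. SKBR3 is a HER2-amplified breast cancer line, commonly described as lacking nuclear estrogen receptor alpha and expressing the membrane estrogen receptor GPER. E2-BSA is widely used as a form of the hormone that does not enter cells, and G15 is an antagonist of GPER. ICI is named only by this abbreviation in the labels. The data comprised 8 arrays, 1 for each of the untreated, ethanol, BSA, estradiol, E2-BSA, G15, E2-BSA plus ICI and E2-BSA plus G15 conditions, all taken after 3 h. Differences are log2 values of 1 array minus another over 19775 genes. No condition was repeated, so no difference below has a replicate check.

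The first comparison addressed what the ethanol vehicle alone does. The ethanol array stood far from the untreated array through inflammatory genes. CCL20, a chemokine, was higher by 7.73 (213-fold), CXCL8, the neutrophil chemokine interleukin 8, by 7.33 (161-fold) and CXCL1 by 6.26 (76.7-fold). Of the 20 measured genes of the inflammatory NF-kB list, 15 were at least 2-fold higher, among them TNF by 5.20, the NF-kB feedback inhibitor TNFAIP3 by 5.17 and IRF1 by 3.69. On no other array did the 20 genes depart in this way: their median lay between -0.089 and 0.049 on the other 7 arrays, each set against the median of the rest without ethanol.

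Other stimulus genes were high on the ethanol array as well. Of 29 immediate early genes, 14 were at least 2-fold higher and the list median was 0.94, with FOS higher by 2.78, ZFP36, which destabilizes inflammatory transcripts, by 2.46, and JUN by 2.02. In the unfolded protein and ATF4 list 7 of 30 genes were at least 2-fold higher, led by PPP1R15A at 3.20 and CHAC1 at 2.59. All 20 genes of the G2/M list were lower, with a median of -0.50, and KIF23 differed by -0.96 and KIF20A by -0.88. Across all genes 172 were at least 2-fold higher and 3 lower, the latter being PSRC1 (-1.14), the unnamed locus LOC441179 (-1.09) and the water channel AQP11 (-1.05). Of the 27 lists, 12 stood apart from random lists, where chance gives 1.35.

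**Figure D1:**
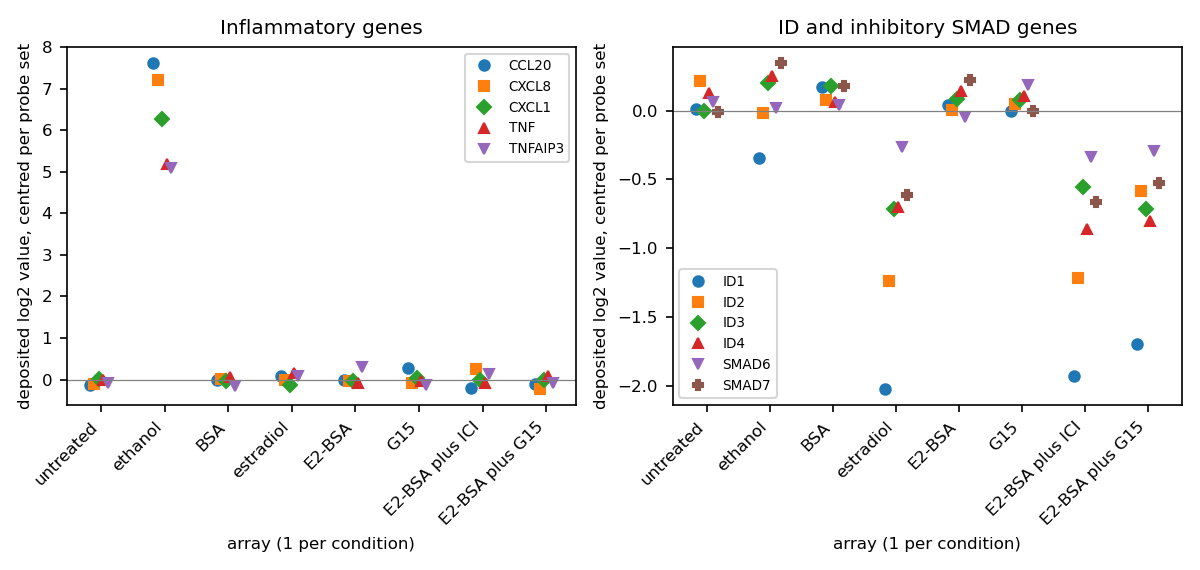
Deposited log2 values, centred per probe set, of 5 inflammatory genes (left) and of 4 ID genes with SMAD6 and SMAD7 (right), 1 point per gene and array, with the array on the x axis. The inflammatory genes are high on the ethanol array alone, with CCL20 at 7.61, and the ID genes are low on the estradiol, E2-BSA plus ICI and E2-BSA plus G15 arrays, with ID1 at -2.02, -1.93 and -1.70.

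The carrier BSA was compared with untreated cells in the same way. Only 6 genes were at least 2-fold higher and 0 lower. They were LOC114224 (1.38), the nuclear noncoding RNA MALAT1 (1.36) and the interferon-inducible IFI27 (1.25) by the naming rule, and LMTK3 (1.17), FTX (1.07) and SLC26A6 (1.03), named after their values were seen. The interferon list had a median of 0.21 with 17 of 21 genes above 0, and the G1/S and DNA replication list a median of -0.12 with 17 of 20 below 0. The MALAT1 difference rests on probe sets that can match several transcripts, and without them it was -0.045. The SD over genes was 0.166 for this pair and 0.304 for ethanol minus untreated, the other pair without hormone or antagonist.

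Free estradiol was compared with its vehicle. Against the ethanol array the estradiol array was lower in 171 genes and higher in 2. Of the 171 lower genes, 150 were at least 2-fold higher on the ethanol than on the untreated array. CXCL1 differed by -6.41, the bacterial sensor NOD2 by -2.91, heme oxygenase HMOX1 by -2.41, NEURL3 by -2.10 and the stress factor ATF3 by -2.02. The cell-cycle inhibitor CDKN1A differed by -1.97, GCNA by -1.94, SESN2 by -1.92, the glycolysis regulator PFKFB3 by -1.83, the mitochondrial superoxide dismutase SOD2 by -1.79 and TNFSF9 by -1.77. The Wnt antagonist DKK1 was higher by 1.52 and AQP11 by 1.12, and both were lowest on the ethanol array, at -1.08 and -1.05. Against the untreated array, CXCL1 differed by -0.15, NOD2 by -0.29, ATF3 by -0.05 and DKK1 by 0.86, while CDKN1A differed by -0.65 and PFKFB3 by -0.45. The inflammatory list had a median of -1.69 against ethanol and 0.05 against untreated.

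Set against the untreated array, the estradiol array was lower in 3 genes at 2-fold and higher in 0. The 3 genes, named here after their values were seen, were ID1 (-2.03) and ID2 (-1.45), which encode inhibitors of helix-loop-helix transcription factors and are known targets of bone morphogenetic protein signalling, and the interferon-induced IFIT1 (-1.25). ID1 and ID2 were also lower against ethanol, at -1.68 and -1.22. Of the other genes of the TGF-beta and YAP list, ID3 differed from untreated by -0.72 and the inhibitory SMAD7 by -0.61, and the list median was -0.22 with 13 of 17 genes below 0. The phosphatase DUSP4 was higher by 0.84, EGR1 by 0.78, FOSL1 by 0.68 and FOS by 0.67. For EGR1, FOSL1 and FOS the untreated array held the lowest value of all arrays. Against BSA these genes, in the order from DUSP4, were higher with estradiol by 0.556, 0.673, 0.275 and 0.447. BSA minus untreated, without hormone, gave 0.281, 0.110, 0.409 and 0.220. The immediate early list had a median of 0.26 against untreated with 22 of 29 genes above 0, beside 0.025 on BSA minus untreated. Against ethanol that list ran the other way, with a median of -0.99, 25 of 29 genes below 0, FOS at -2.11 and EGR1 at -1.05. Against untreated the GPER-linked list stood at 0.08, beside 0.09 on BSA minus untreated without hormone, the cAMP list at 0.11, the short-lived transcripts at 0.05, the interferon list at -0.07, the G1/S list at -0.06 and the G2/M list at -0.12 with 19 of 20 genes below 0, all apart from random lists. The list of nuclear estrogen receptor targets had a median of -0.02 against untreated and 0.05 against ethanol, in both cases inside the range of random lists. The count of 173 genes against ethanol thus stood beside 3 against untreated and 7 against BSA.

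**Figure D2:**
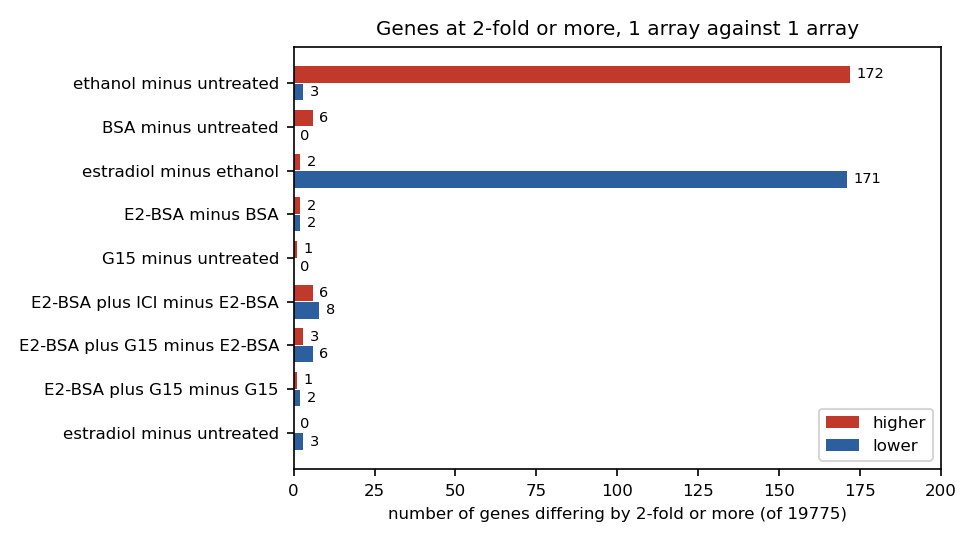
Number of genes, of 19775, that differed by 2-fold or more in each comparison of 1 array with 1 array, with the comparison on the y axis, higher in red and lower in blue. Both comparisons with many genes, 172 higher in ethanol minus untreated and 171 lower in estradiol minus ethanol, involve the ethanol array.

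E2-BSA was compared with its carrier to show what the coupled hormone does. Only 4 genes differed by 2-fold or more, and for each the BSA array held the highest or the lowest of the 8 values. IFI27 differed by -1.28 and was the only gene whose difference was larger than the range of the untreated, ethanol and BSA arrays. MALAT1 (-1.17), the lipid phosphatase gene PLPP3 (1.18) and INTU (1.11) are named after their values were seen. Against the untreated array no gene reached 2-fold with E2-BSA, and IFI27 differed by -0.04. ID1 differed from untreated by 0.03, ID2 by -0.21 and ID3 by 0.09, unlike with free estradiol.

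Small shifts of 6 gene lists were seen against BSA, and none of these lists stood apart against untreated. The unfolded protein and ATF4 list had a median of 0.11 against BSA with 28 of 30 genes above 0, the G1/S list 0.13 with 17 of 20 above 0, and the histone list 0.14 with 8 of 9 above 0. The heat shock list stood apart at 0.13, the aryl hydrocarbon receptor list at 0.12 and the glucocorticoid receptor list at 0.14. No gene of these 6 lists reached 1.5-fold. Against untreated the medians were 0.06 for the unfolded protein list, -0.001 for G1/S, 0.00 for histones, 0.03 for heat shock, 0.001 for the aryl hydrocarbon receptor and 0.08 for the glucocorticoid receptor. Other lists stood apart from random lists on E2-BSA minus untreated: interferon at 0.17 with 17 of 21 genes above 0, short-lived transcripts at 0.10 with 20 of 24, immediate early genes at 0.09 with 22 of 29, the inflammatory list at 0.08 with 15 of 20, and immune cell markers at -0.135. The carrier alone, BSA minus untreated, gave 0.215, 0.039, 0.025, 0.036 and -0.155 for these lists. On E2-BSA minus BSA they stood at -0.012, 0.003, 0.007, 0.019 and 0.030, and none stood apart. On BSA minus untreated all 6 medians of the first lists were below 0, in the same order -0.02, -0.12, -0.15, -0.09, -0.05 and -0.02. Among the GPER-linked genes CCN2, a secreted matrix protein, differed by 0.58, EGR1 by 0.11 and FOS by -0.03, and the list median was -0.03.

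Free and coupled hormone were each given at a stated 1e-06 M for the same time. They differ in structure by the albumin to which the hormone is attached. Whether the E2-BSA figure counts the conjugate or its estradiol was not resolved here, so an equal hormone dose is not established. In the direct comparison estradiol minus E2-BSA, 3 genes were lower at 2-fold and 0 higher, with an SD over genes of 0.163. They were ID1 (-2.06), IFIT1 (-1.59) and ID2 (-1.24), named after their values were seen. On ethanol minus untreated, the vehicle of estradiol, ID1 differed by -0.35, IFIT1 by 0.15 and ID2 by -0.24. With 1 array each, no interval rests on replicates of these conditions. With the spread of the ligand-free arrays in limma, a step added after the values were seen, the 95% intervals were -2.83 to -1.29 for ID1, -2.00 to -1.18 for IFIT1 and -1.67 to -0.81 for ID2. They are not adjusted for the choice of these genes, and 0 genes had an adjusted p under 0.05. The responses to the 2 forms, each against its own reference, correlated negatively across genes (Pearson r = -0.301, Spearman rho = -0.360), and r was -0.058 with estradiol set against untreated.

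G15 alone was compared with untreated cells. LMTK3, a kinase gene, was higher by 1.25 and was the only gene at 2-fold, and it differed by 0.08 from the BSA array. Of the immediate early list, SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, differed by -0.70 and was the only member at 1.5-fold. The hypoxia and glycolysis list had a median of -0.10 with 15 of 19 genes below 0, the cholesterol list -0.09 with 13 of 18 below 0, and INSIG1 of that list differed by -0.54. The unfolded protein list stood at -0.05, the G1/S list at -0.07 and the endothelial marker list at 0.14, with 6 of 8 of its genes above 0. On BSA minus untreated, without antagonist, the G1/S list stood apart too, at -0.119. The hypoxia (0.043), cholesterol (-0.026), unfolded protein (-0.025) and endothelial (0.017) lists did not stand apart there. ID1 differed by -0.01 and ID2 by -0.17.

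E2-BSA with ICI was compared with E2-BSA alone to show what the antagonist alters. ID1 (-1.97), ID2 (-1.22) and, just past 2-fold, ID4 were lower, as were RAC3 (-2.09), C3orf33 (-1.92), LINC02893 (-1.01) and the interferon-related IFIT1 (-1.89) and SAMD9 (-1.02). Higher were OR10H3 (1.18), YPEL3-DT (1.14), FAM111B (1.13), MIR4755 (1.10), the cohesin acetyltransferase ESCO1 (1.01) and, just past 2-fold, ANKRD36B. For ID4, 3 of 5 probe sets were lower, and the 3 probe sets of ESCO1 ranged from 0.0005 to 1.86. Against the BSA array OR10H3 was higher by 0.38, YPEL3-DT by 0.23 and MIR4755 by 0.43, while ID1 differed by -2.10 and RAC3 by -1.64. SAMD9 differed by -0.495 from BSA and by -0.632 from untreated.

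The interferon list was lower with ICI, at a median of -0.28 with 16 of 21 genes below 0, 7 of them by 1.5-fold or more, including IFIT3 (-0.91), OAS1 (-0.88) and IFI44L (-0.77). The IFIT3 value rests mostly on 1 of 2 probe sets, at 0.926 with E2-BSA and -0.746 with ICI added. The other stood at -0.071 and -0.229. Against BSA the interferon list had a median of -0.39, where BSA minus untreated gave 0.215. The TGF-beta and YAP list had a median of -0.28 with 15 of 17 genes below 0, SMAD7 at -0.88 and ID3 at -0.65. The cAMP list stood at 0.21 with 13 of 16 genes above 0, and the immediate early list at 0.10, with EGR1 at 0.79 and DUSP4 at 0.62. The unfolded protein (-0.09), G1/S (-0.11) and hypoxia (-0.11) lists stood apart below random lists. Against BSA the unfolded protein list stood at 0.026, G1/S at -0.003 and the immediate early list at 0.053, none of them apart. The hypoxia (-0.063), cAMP (0.146) and TGF-beta and YAP (-0.124) lists stood apart against BSA too. In total 6 genes were higher and 8 lower.

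E2-BSA with G15 was compared with E2-BSA alone and with G15 alone. Against E2-BSA, RAC3 differed by -1.98, ID1 by -1.74, KANK4 by -1.22 and the homeobox gene HOXC13 by -1.07, and CCDC186 (1.21), FAM111B (1.12) and KIF21A (1.10) were higher. SOX9 (-1.06), named after its value was seen, and CCN2 (-1.01), of the GPER-linked list, also reached 2-fold. Both lay below the untreated, ethanol and BSA arrays, with a difference smaller than the range of those 3, which the ethanol array widens. KANK4 was highest with E2-BSA, at 0.544, and with G15 added differed by -0.706 from untreated and by -0.705 from BSA. For KIF21A 1 of 2 probe sets was higher. The 3 probe sets of CCDC186 were higher by between 0.14 and 2.88, and the highest of them stood at 1.60 with G15 alone and at 0.48 on BSA. Against G15, ID1 differed by -1.70, RAC3 by -1.51 and MATR3, a nuclear matrix protein gene, by 1.01. The counts were 3 higher and 6 lower against E2-BSA, and 1 higher and 2 lower against G15.

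The TGF-beta and YAP list was lower with G15 added to E2-BSA, at -0.28 against E2-BSA with 15 of 17 genes below 0, and at -0.18 against G15 alone with 13 of 17 below 0. SMAD7 differed by -0.75 and ID3 by -0.80 against E2-BSA, and by -0.53 and -0.79 against G15. Against E2-BSA the inflammatory list stood at -0.17 with IRF1 at -0.55, the short-lived transcripts at -0.13, the interferon list at -0.13, the immediate early list at -0.09, the glucocorticoid receptor list at -0.16, the fatty acid synthesis list at -0.15 and the unfolded protein list at -0.10. None of these lists stood apart against G15 alone, with medians in the same order of -0.081, -0.008, -0.063, 0.029, -0.022, -0.030 and -0.016. Against BSA only the interferon list stood apart, at -0.165. Against G15 the GPER-linked list stood at -0.15, the heat shock list at 0.10 and the luminal breast list at 0.12.

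Set side by side, the antagonist combinations differed in 2 genes at 2-fold: E2-BSA plus ICI minus E2-BSA plus G15 gave C3orf33 at -1.55 and ALPP, a placental-type phosphatase gene, at 1.01, both named after their values were seen. Against the BSA array, E2-BSA plus ICI was lower in 6 genes and E2-BSA plus G15 in 3. Of the receptors, ESR1 lay between -0.096 and 0.092 over the 8 arrays, ESR2 between -0.050 and 0.117, ERBB2 between -0.214 and 0.146, and GPER1 between -0.281 (E2-BSA plus G15) and 0.084 (G15). These means cover probe sets that disagree. For ERBB2 1 probe set ran from -0.601 (E2-BSA plus ICI) to 0.368 (BSA) and another from -0.071 to 0.028. The GPER1 probe sets stood at -0.524 and -0.039 with E2-BSA plus G15, and 1 of ESR1 at 0.469 with ethanol.

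The G15 responses without and with E2-BSA correlated across genes at r = 0.243 (rho = 0.232), and the ICI response on E2-BSA correlated with the G15 response at r = 0.306 (rho = 0.310). The BSA and estradiol responses, as a pair with no hormone on one side, gave r = 0.104 (rho = 0.144). No batch is given in the labels, and with 1 array per condition no value within a batch can be had. In an added pair, estradiol minus untreated and E2-BSA plus ICI minus BSA shared ID1, ID2 and IFIT1 among 3 and 6 lower genes, while r across all genes was 0.059. With E2-BSA plus G15 minus BSA only ID1 was shared, and r was -0.010. Neither pair was planned, so these overlaps describe the arrays and are not set against chance.

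The E2-BSA response was followed onto the antagonist arrays through its 4 genes at 2-fold. Their median difference from the mean of the untreated and ethanol arrays, signed by the direction of the response, was -0.05 on the E2-BSA array itself, -0.58 with ICI, -0.70 with G15 added, -0.63 with G15 alone and -0.05 with free estradiol. The response of these genes against BSA was therefore not seen against the untreated and ethanol arrays, and its loss with an antagonist cannot be measured. With the 198 genes at 1.5-fold the values were 0.24, -0.19, -0.17, -0.23 and -0.12. The genes were chosen on the E2-BSA and BSA arrays, which raises the value of E2-BSA and lowers those of arrays that resemble BSA. Across all 54675 probe sets the centred values of BSA correlated with those of G15 at 0.223, of E2-BSA plus ICI at 0.182 and of E2-BSA plus G15 at 0.0951. This correlation was not taken over genes. With this resemblance to BSA, the negative values of these arrays on the chosen genes do not measure antagonism.

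**Figure D3:**
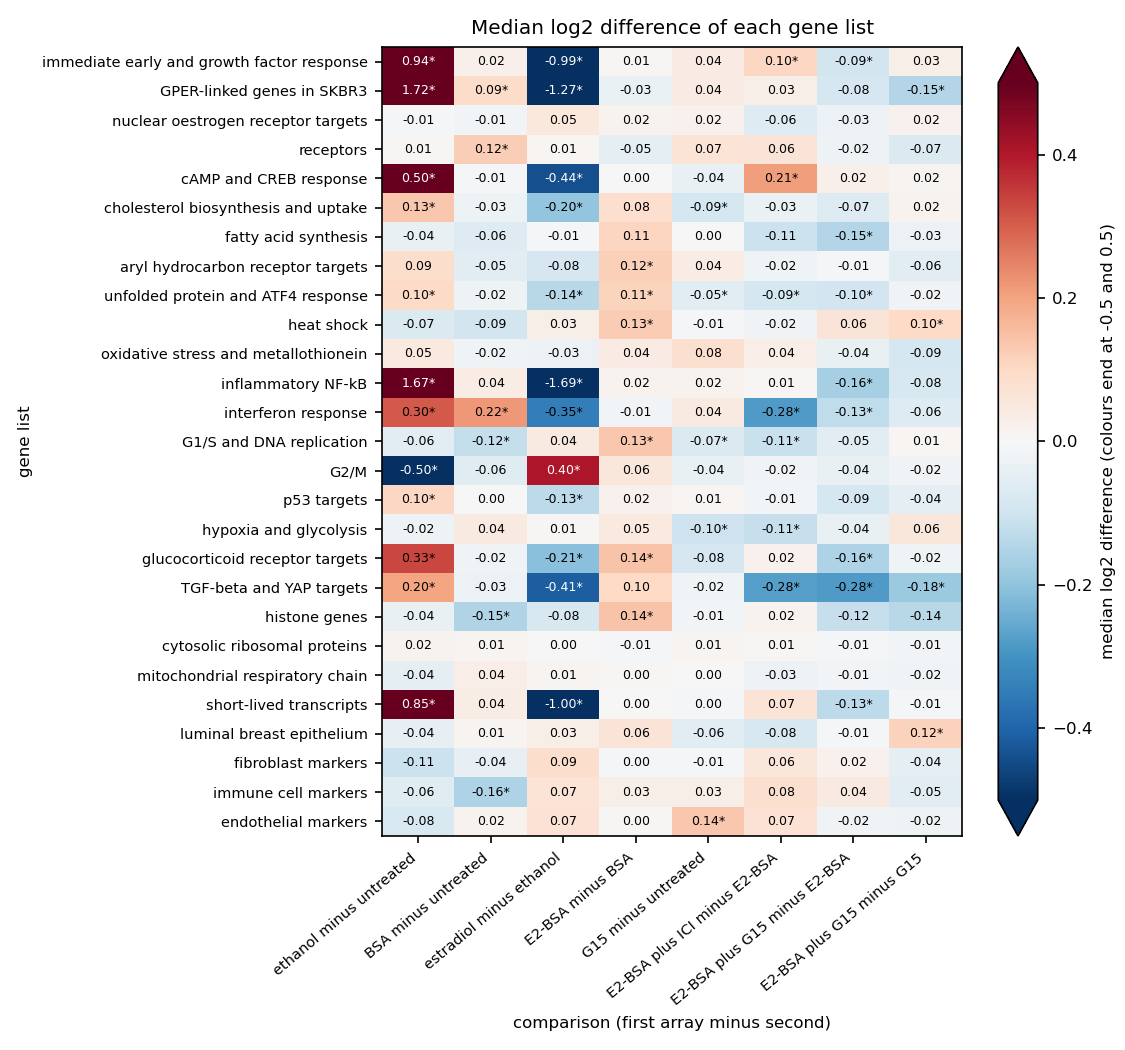
Median log2 difference of each of the 27 gene lists (rows) in the 8 comparisons (columns), with colours that end at -0.5 and 0.5 and a star where the list stands apart from random lists. Of 216 medians 60 carry a star, where chance gives 10.8, and the inflammatory list reaches 1.67 in ethanol minus untreated.

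Over all comparisons 60 of 216 list medians stood apart, against 10.8 for random lists. The comparisons with the ethanol array gave 12 each, and BSA minus untreated, without hormone or antagonist, gave 6 of 27, as many as E2-BSA minus BSA and more than the 5 of G15 minus untreated. Cytosolic ribosomal proteins and the mitochondrial respiratory chain stood apart in none of the 8 comparisons, with medians between -0.014 and 0.018 and between -0.044 and 0.035. Nuclear estrogen receptor targets, oxidative stress genes and fibroblast markers did not stand apart in any either. Immune cell markers stood apart once, at -0.15 in BSA minus untreated, and the receptor list once, at 0.12 in the same comparison.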

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

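Of the tests in this part, only the marker test of other cell types was chosen before its result was seen, and the tests of the ethanol, of a stimulus, of the ID genes and of the shared shift in the form that decided it were chosen afterwards. To keep to 3 explanations per pattern, 4 tests that had been run were left out of the table after their results were seen. They were a scaling fault of the ethanol array (inflammatory list median 1.67, above all random lists), a label exchange of the ethanol array within the 8 arrays, a fault of single ID probe sets (7 of 9 low on all 3 arrays), and RNA integrity. The exchange test was void, since the highest list median on another array, 0.049, would be the same under any exchange. The last compared array groups defined from the data, and the actin 3' minus 5' values ran from -0.372 with E2-BSA plus G15 to 0.279 with ethanol.

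A probe set without a gene name (ID 1558048_x_at), which entered no comparison, was far higher on the estradiol array than on any other. It stood at 6.32 with estradiol, which is 6.33 above the highest of the untreated, ethanol and BSA arrays, and at 0.55 or less on the remaining arrays. It belongs to 13522 probe sets outside the comparisons because they carry no gene name or several, of which 3 lay at least 2-fold above the ligand-free range on the estradiol array. No explanation was tested for it.

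Inflammatory genes were high on the ethanol array alone, 15 of 20 by at least 2-fold. RNA of other cells would bring their own transcripts, but 26 measured markers of immune, endothelial and fibroblast cells had a median of -0.084, with PTPRC at -0.12, PECAM1 at -0.27, COL1A1 at -0.01, CDH5 at 0.16 and CLDN5 at 0.32, although SELE, an endothelial gene outside these lists, was higher by 5.87. Ethanol itself would be expected on the estradiol array too, whose vehicle it was per the labels, and there the inflammatory list had a median of 0.047 against untreated. An inflammatory stimulus in that culture, or a sample from elsewhere under the label, may lie behind it and cannot be told apart, since no second ethanol array exists here. An exchange of labels among the 8 arrays stays open too, and estradiol opposing the ethanol response remains a further, biological possibility.

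ID1, ID2, ID3 and ID4 were low with estradiol, with E2-BSA plus ICI and with E2-BSA plus G15, by a mean of -1.26, -1.23 and -1.04 against untreated, and at -0.02 with E2-BSA alone. A shift common to the G15 and BSA arrays and the combinations is argued against by the means on G15 and BSA, which lay within 0.034 of untreated. If the E2-BSA label had been exchanged with that of a hormone-free array, 1 of those would be low, and the lowest of the untreated, ethanol, BSA and G15 means was -0.052 from their median. An exchange of the estradiol and E2-BSA labels, which differ by -1.24 in these genes, would place the ID genes low in every culture with E2-BSA and normal in that with free estradiol, and it cannot be told apart because no transcript on the arrays reports the compound. The ribosomal RNA control HUMRGE was low in its middle probe set with estradiol (-0.391), E2-BSA plus ICI (-0.794) and E2-BSA plus G15 (-0.575). It was read afterwards, and stood at 0.000 with E2-BSA and -0.254 with G15. Another probe set gave -0.326, -0.554 and -0.410, against 0.000 and -0.106. In the remaining one estradiol stood at 0.000, above G15 (-0.194) and BSA (-0.148). A part of RNA composition or quality in the low ID genes was not tested. A hormone effect that E2-BSA alone lacks at 3 h is a biological candidate for the estradiol array, and it is untested without repeats. It does not account for the low ID genes with E2-BSA plus ICI and E2-BSA plus G15. Whether the antagonists act on them in the presence of E2-BSA was not tested, and no array of ICI alone was analysed here.

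Genes that set the antagonist arrays apart also tended to differ on the BSA array, which had no antagonist. As first written, with 200 genes chosen on 6 arrays, the signed median on BSA minus untreated was 0.071. Of these, 134 of 200 genes lay in the direction of their selection. For E2-BSA minus untreated the values were -0.132 and 40 of 200, here and below on another 200 genes, chosen without E2-BSA and with BSA. By the bound of 0.1 written for this test, 0.071 spoke for an effect of the antagonists and against an unlabelled processing batch. That bound was not used, because 109 of the 200 genes behind the 0.071 were at 2-fold in ethanol minus untreated. The choice thus mostly measured the ethanol array. The selection without ethanol, and the rule that replaced the first by it, were chosen after both values were seen: the median was then 0.171, with 151 of 200 genes in that direction, against 0.000 and 94 of 200 for E2-BSA minus untreated. The bacterial spike-in control bioB, read afterwards, had means of 0.297 on G15, 0.452 on E2-BSA plus ICI and 0.341 on BSA, but -0.017 on E2-BSA plus G15, against 0.157 on untreated, -0.016 on ethanol, -0.145 on estradiol and -0.225 on E2-BSA. The 0.171 lies between the bounds of 0.1 and 0.2, and bioB follows the shift on 3 of its 4 arrays, so the antagonists and a processing batch cannot be told apart, and either could contribute to the correlations between antagonist responses.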

How the results depend on the processing

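Settings named as added in the methods were chosen after seeing the data. Median centring of each array left all counts within 1.5 times and all correlations within 0.1. The counts below follow the order ethanol, BSA, estradiol, E2-BSA, G15, E2-BSA plus ICI, E2-BSA plus G15 against E2-BSA, and the same against G15. With the probe set of largest SD for each gene they were 343, 66, 324, 78, 55, 122, 70 and 25, the G15 correlation was 0.346, and the response kept with G15 was -0.49. The balance of directions was not always kept: higher and lower genes were 33 and 33 for BSA, 73 and 49 for E2-BSA plus ICI, 47 and 23 for E2-BSA plus G15 against E2-BSA and 21 and 4 against G15, and at 1.5-fold 70 and 40, 204 and 112, 86 and 71, and 26 and 71. For E2-BSA against BSA they were 66 and 12 with the probe set of largest SD, and 67 and 131 at 1.5-fold. For G15 against untreated they were 30 and 25, and 72 and 33. At 1.5-fold the counts were 732, 110, 673, 198, 105, 316, 157 and 97, and the responses kept were -0.19 with ICI and -0.17 with G15. Without probe sets of shared sequence those responses were -0.10 and -0.44, and MALAT1 on BSA against untreated turned to -0.045 (from 1 probe set). The cause of these changes was not tested. The comparator decided several counts. Against untreated, estradiol gave 3 genes and E2-BSA 0, and the response kept with ICI was -0.13. The correlation of the hormone forms was -0.058 with only estradiol set against untreated and -0.258 with only E2-BSA. Against BSA, estradiol gave 7 genes, E2-BSA plus ICI 9 and E2-BSA plus G15 4. Against ethanol, E2-BSA gave 149 and G15 243, the cause being the ethanol array. Against the mean of the ligand-free arrays the counts were 13 for estradiol, 9 for E2-BSA, 15 for G15 and 28 for E2-BSA plus G15. Against the mean of untreated and BSA they were 3, 0, 0, 7 for E2-BSA plus ICI, and 4. limma called 0 genes at an adjusted p under 0.05 in all 6 comparisons with a hormone or antagonist, with and without the ethanol array, where 197, 436, 581, 1042, 555 and 502 genes had an unadjusted p under 0.05 with it and 458, 1380, 933, 2030, 1374 and 1095 without it, where chance gives 989. That fit has 2 residual degrees of freedom, 1 without ethanol, and assumes that each lone array varies like the ligand-free ones. The absence of called genes therefore does not show that no gene changed. List medians that stood apart numbered 45 to 60 under the probe set and centring alternatives. Of 291 values recomputed for named genes, 163 stayed within 0.166, 127 moved by more, 111 of these towards 0, and 1 turned. Quantile normalization, filters on low values and floors were not run, because the values are centred. Without level or background, it is unknown which genes were above background. No paired analysis was possible because each group has 1 array.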

Other observations

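Tests in this part were not planned and are reported as values only. Further single genes were high on the ethanol array. SELE, the adhesion molecule E-selectin, was higher by 5.87 than on the untreated array, and the interferon-inducible chemokine CXCL10 by 2.86, both chosen after their values were seen. Among the p53 targets GADD45A was higher by 2.52, CDKN1A by 1.32 and the death receptor TNFRSF10B by 1.04, while the list median was 0.10. SGK1 and CEBPD of the glucocorticoid receptor list were higher by 1.89 and 1.70, and the insulin receptor substrate IRS2 by 2.37. In the cholesterol list HMGCS1 was higher by 0.95 and STARD4 by 0.69, and 12 of 18 genes lay above 0.

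Further genes followed the ID genes across the arrays, chosen after their values were seen. DLX1, DLX2 and DLX3, homeobox genes, stood at -0.42, -0.52 and -0.65 with estradiol, at -0.25, -0.71 and -0.61 with E2-BSA plus ICI and at -0.41, -0.49 and -0.37 with E2-BSA plus G15. With E2-BSA alone they stood at 0.14, -0.03 and 0.15. SMAD6 stood at -0.26, -0.33 and -0.29 on the first 3 of these arrays and at -0.05 with E2-BSA alone. The means of SMAD6, DLX1 and DLX2 rest mostly on 1 probe set each. For SMAD6 that probe set stood at -0.836, -0.955 and -0.883 while another of its 4 stood at 0.000, -0.083 and 0.000, and the other probe set of DLX1 stood at -0.015, 0.331 and 0.055. EDN2, an endothelin, stood at -0.55, -0.45 and -0.59, and at 0.31 with E2-BSA alone. Of 9 ID probe sets, 7 lay below every ligand-free array on all 3. RAC3 did not follow this pattern: it stood at 0.00 with estradiol, 0.44 with E2-BSA, -0.03 with G15, -1.65 with E2-BSA plus ICI and -1.54 with E2-BSA plus G15.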
